A study of Mus musculus with 31 samples.

How the data were processed

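Liver RNA of 31 male C57BL/6 mice aged 3 to 4 months was hybridized by the authors to Affymetrix whole-transcript mouse arrays with 1 biotin label, from 100 ng of total RNA per sample. Per the labels, mice were exposed to 2 fasts of 16 h over 8 weeks or, in a cohort of 24 mice, to none, and were then sampled in the morning either fed or after a 16 h fast. Each column was read as 1 animal, and no 2 arrays were identical (Pearson's r between arrays 0.976 to 0.993). The design crosses the number of earlier fasts (0 or 2) with the final state, in groups of 8, 8, 8 and 7 arrays. The labels give no processing batch.

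The deposited values are in log2 units, made by the authors with RMA, which corrects background, normalizes quantiles and summarises probe sets on a log2 scale. The version of RMA is not given in the sources used here. Values ran from -0.0139 to 13.1 with column medians of 2.01 to 2.07, and were not centred per probe set. The log base is that of RMA and could not be set against scanner signals. Detection calls and background signals were not used here, so no limit of detection is given for a single gene, and dim genes were handled only by an alternative filter.

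The platform's annotation named 1 gene symbol for 23521 of 41345 probe sets, several for 1814 and none for 16010. Of the 23521, 23328 had an Entrez identifier in the RefSeq annotation of GRCm38.p6, all 23328 with an unchanged symbol. That annotation was used only for names, and since the platform's annotation names no genome build, no coordinates are printed. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene, which gave 22180 genes. Probe sets with several symbols or none were tested apart.

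All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 with version 1.17.8 of the data.table package, as group means with moderated variances, and 6 comparisons were made. These are the response to the final fast with 0 and with 2 earlier fasts, the difference between histories in fed and in fasted mice, the interaction of history and final state, and the history effect averaged over both states. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison, 2-sided. Tests of array means were 2-sided permutation tests, exact between 2 groups and with 1e+05 resamples within strata. Correlations across genes are descriptive. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

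The 25 pathway lists and 10 cell type marker lists were chosen before the data were examined, as were the comparisons, thresholds, named-gene rule and all alternatives not marked otherwise. The annotation measured 597 of their 662 entries. Some genes belong to several lists, such as Cyp4a14, Got1 and Per1, so lists are not independent. The lists cover fatty acid oxidation, PPAR-alpha targets, ketogenesis, gluconeogenesis, glycolysis and lipogenesis, cholesterol biosynthesis, insulin and FoxO signalling, the urea cycle and amino acid catabolism, bile acids, xenobiotic metabolism, the circadian clock, glucocorticoid-responsive genes, autophagy, the unfolded protein response, heat shock proteins, the cell cycle, the acute phase, interferon response, antigen presentation, chromatin modifiers, male-biased and female-biased liver genes, immediate early genes, ribosomal proteins and the respiratory chain. The markers cover Kupffer, sinusoidal endothelial, stellate, cholangiocyte, lymphocyte, neutrophil and monocyte, erythroid, adipocyte, exocrine pancreas and skeletal muscle cells. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over 35 lists within a comparison, and again with an estimated correlation. List members were also adjusted over the list alone. That adjustment does not allow for the number of lists, so over 35 lists a few such calls can arise by chance.

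Genes are named by a fixed rule. It takes the 12 largest rises and 12 largest falls among called genes of each response to the final fast, up to 4 called members of each list with the largest changes, and the 5 smallest p of a comparison with fewer than 5 calls, leaving out predicted and numbered gene models. It also takes a fixed list of genes in every comparison, of which Pck1, G6pc, Cyp7a1, Fgf21, Cyp4a14, Srebf1 and Fasn are given and the others are not reported here. Genes outside the rule are Ccna2, Mx2 in fasted mice, Cebpd in the interaction, Rnd3 and 1700025C18Rik, Gadd45g in mice with 2 earlier fasts, Arhgap31 and Ccnjl in the responses, and the genes of single arrays, all chosen after their values were seen.

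The analysis was tested on simulated data with 200 genes changed in each of 10 draws per comparison. It recovered 98.8, 98.2, 99.6, 97.6, 91.8 and 99.4% of 2-fold changes in the 6 comparisons in the order above, 83.4, 83.4, 83.2, 80.4, 52.2 and 95.8% of 1.5-fold changes, and 22.6, 15.0, 20.4, 15.0, 5.8 and 45.2% of 1.2-fold changes. False calls made up 4.81 to 5.63% of calls. A shift of 0.3 given to 1 list was recovered, with 0 other lists called. Simulated genes varied independently, so this cannot show how often genes that vary together give false list calls. The recovery rates hold for 200 genes changed by 1.2-fold to 4-fold. They may be lower where fewer genes change, since the adjustment is then stricter.

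Alternatives were an intensity trend with robust variances, array weights, a fit of only the groups compared, the replicate number as a block, cyclic loess normalization, leaving out dim genes (mean under the 40th percentile), the mean of all probe sets of a gene, an adjusted p under 0.01, an estimated correlation in camera, and leaving out each array in turn. A test of list means per array, an adjustment over only the genes called for the mean fasting response, and a fit of all probe sets were added after seeing the data. Whether arrays with the same replicate number deviate together was tested with 10000 permutations of the numbers within groups, and the intervals of correlations across fed arrays were taken from 10000 bootstrap draws, both added after seeing the data. Arrays far from their group were sought with Dixon's ratio in 32 genes with the largest changes or on the fixed list, and in 6 measures per array. Each comparison was repeated on 100 splits of its arrays, the real one included.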

Results

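Liver RNA was profiled in 31 male C57BL/6 mice aged 3 to 4 months, 1 array per animal, on Affymetrix whole-transcript arrays. Livers were taken in the morning, in the fed state or at the end of a 16 h fast. Before that final state, mice had been through either 0 or 2 earlier fasts of 16 h within 8 weeks. The groups held 8 fed and 8 fasted mice with 0 earlier fasts, and 8 fed and 7 fasted mice with 2 earlier fasts. Values were RMA log2 signals for 22180 genes, from -0.0139 to 13.1, with array medians of 2.01 to 2.07. The number of arrays limits the precision of every value. On the first principal component, which held 30.42% of the variance, fed arrays lay between -24.23 and -18.09 and fasted arrays between 14.39 and 36.82.

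The response to the final fast in mice with 0 earlier fasts asks what a single 16 h fast does to liver transcripts. Cyp4a14, a fatty acid hydroxylase and a target of the nuclear receptor PPAR-alpha, went from 5.64 ± 1.84 in fed mice to 12.14 ± 0.11 in fasted mice (log2, mean ± SD, n = 8 and 8), which is 90.4-fold (log2 change 6.50, SE 0.52, adjusted p = 1.23e-11). Cidec, which codes for a lipid droplet protein, rose by 5.24 (SE 0.26, adjusted p = 2.2e-16). Hsd3b5, a steroid dehydrogenase typical of male liver, fell by 5.22 (SE 0.34, adjusted p = 1.18e-13), and Fdps, which makes farnesyl diphosphate for sterol synthesis, fell by 3.59 (SE 0.14, adjusted p = 7.11e-19). The fasted values of Cyp4a14, 11.98 to 12.33, lie near the top of the signal range, where an array may compress differences. The probe sets behind these values are 17428457 for Cyp4a14, 17469754 for Cidec, 17408315 for Hsd3b5 and 17406908 for Fdps.

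Of 25 measured fatty acid oxidation genes, 23 rose and 0 fell, with 23 also called when adjusted over the list alone and a median log2 change of 0.82. Ehhadh, an enzyme of peroxisomal beta-oxidation, rose by 2.80, Crat, which forms acetylcarnitine, by 2.31 (1.5 with the mean of its probe sets), Cpt1a, the carnitine transferase that admits long-chain fatty acids to mitochondria, by 1.36, and Slc25a20, the carnitine-acylcarnitine carrier, by 1.25. Of 28 PPAR-alpha targets, 25 rose and 1 fell, with 26 called when adjusted over the list alone and a median of 1.43. Among them the acyl-CoA thioesterase genes Acot1 and Acot2 rose by 4.62 and 4.35, and Fgf21, a hormone of the fasted liver, rose by 2.04 (SE 0.31, adjusted p = 7.82e-06). Of 4 measured genes of ketogenesis and ketone transport, 3 rose and 1 fell, and all 4 were called when adjusted over the list alone, with a median of 0.45. Slc16a1, a monocarboxylate transporter, rose by 1.09 and Slc16a6, a related transporter, fell by 0.56. Of 16 gluconeogenesis genes, 12 rose and 0 fell, with 14 called when adjusted over the list alone and a median of 0.47. Pck1, the gene of phosphoenolpyruvate carboxykinase, rose by 1.26 (SE 0.14, adjusted p = 8.94e-09), Got1 by 1.15 and Gpt2, both aminotransferase genes, by 1.08. G6pc, the gene of glucose-6-phosphatase, did not pass (log2 change 0.30, SE 0.15, adjusted p = 0.23). With limma's camera test and an estimated correlation between genes, adjusted p = 7.43e-06 for fatty acid oxidation, 3.27e-05 for PPAR-alpha targets, 0.0111 for ketogenesis and 0.000106 for gluconeogenesis.

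Genes of lipid and sterol synthesis moved the other way. Of 26 genes of glycolysis and lipogenesis, 23 fell and 1 rose, with 24 called when adjusted over the list alone and a median of -0.87. Thrsp, a regulator of lipogenesis, fell by 3.55, Aacs, which activates acetoacetate for lipid synthesis, by 3.29, Fasn, the fatty acid synthase gene, by 3.03 (SE 0.22, adjusted p = 7.96e-13), and Srebf1, a transcription factor of lipogenic genes, by 2.93 (SE 0.19, adjusted p = 5.62e-14). Of 20 cholesterol biosynthesis genes, 18 fell and 0 rose, 18 also when adjusted over the list alone, with a median of -2.01. Sqle, the squalene epoxidase gene, fell by 3.45, Nsdhl, which acts later in the sterol pathway, by 3.05, and Insig1, an endoplasmic reticulum protein that restrains sterol synthesis, by 3.03. With an estimated correlation, adjusted p = 0.00172 for glycolysis and lipogenesis and 0.000106 for cholesterol biosynthesis. Fabp5, a fatty acid binding protein, fell by 3.33 (-2.35 with the mean of its probe sets), Aqp8, a water channel, by 2.81, and the pseudogene Serpina4-ps1 by 3.65.

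Of 17 glucocorticoid-responsive genes, 15 rose and 0 fell, 15 also when adjusted over the list alone, with a median of 1.03 (adjusted p = 0.00135 with an estimated correlation). The metallothionein genes Mt2 and Mt1, which bind metals, rose by 4.63 and 3.85, Gadd45g, a stress-response gene, by 3.04, and Cdkn1a, a cyclin-dependent kinase inhibitor, by 2.84. Fasted replicate 5 with 0 earlier fasts had the highest Mt2, Gadd45g and Cdkn1a of its group, and without it these rose by 4.44, 2.79 and 2.52. Of 19 male-biased liver genes, 13 fell and 0 rose, with 17 called when adjusted over the list alone and a median of -0.70 (adjusted p = 0.00717 with an estimated correlation). Besides Hsd3b5, Selenbp2 fell by 2.52 and Nudt7, a peroxisomal CoA diphosphatase, by 2.17. Of 19 female-biased genes, 5 rose and 1 fell, with 6 called when adjusted over the list alone and a median of 0.04 (adjusted p = 0.028, and adjusted p = 0.0794 with an estimated correlation). The risers include Cyp4a14 and Acot3, which are also PPAR-alpha targets, and Cyp17a1, a steroid hydroxylase, up by 3.71. Without fasted replicate 4 with 0 earlier fasts, the adjusted p for that list was 0.0514. Of 22 cell cycle genes, 3 fell and 0 rose, with 5 called when adjusted over the list alone and a median of -0.14 (adjusted p = 0.0136 with an estimated correlation). Ccnd1, the gene of cyclin D1, fell by 0.55 and Mcm6, a replication helicase gene, by 0.46.

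Of 23 genes of the unfolded protein and integrated stress response, 12 fell and 2 rose, with 19 called when adjusted over the list alone and a median of -0.47 (adjusted p = 3.27e-08, and adjusted p = 0.157 with an estimated correlation). Sdf2l1 and Hyou1, both chaperone genes of the endoplasmic reticulum, fell by 1.78 and 1.19. Of 24 genes of the urea cycle and amino acid catabolism, 13 rose and 3 fell, with 17 called when adjusted over the list alone and a median of 0.29 (adjusted p = 0.000189, and adjusted p = 0.168 with an estimated correlation). Asl, the argininosuccinate lyase gene, rose by 1.24 and Aass, of lysine breakdown, by 1.23. Of 20 autophagy and lysosome genes, 5 rose and 2 fell, with 11 called when adjusted over the list alone and a median of 0.13 (adjusted p = 0.00575, and adjusted p = 0.0794 with an estimated correlation). Bnip3, a mitophagy receptor, rose by 1.12 and Ulk2, an autophagy kinase, fell by 0.56. Of 11 heat shock protein genes, 3 rose and 0 fell, with 4 called when adjusted over the list alone and a median of 0.21 (adjusted p = 0.0119, and adjusted p = 0.381 with an estimated correlation). The heat shock call was also lost with a permutation of array means (adjusted p = 0.126). Hspb1, a small heat shock protein, rose by 0.84 (0.545 with the mean of its probe sets). Of 16 immediate early genes, 5 rose and 0 fell, with 6 called when adjusted over the list alone and a median of 0.50 (adjusted p = 0.00354, and adjusted p = 0.249 with an estimated correlation). Btg2, an antiproliferative gene, rose by 1.07 and Zfp36, which codes for an mRNA-destabilising protein, by 0.77. Fasted replicate 5 with 0 earlier fasts had the highest immediate early gene mean (5.16 against 3.84 to 4.38) and the highest Btg2 (6.15 against 4.01 to 4.92) of its group. Without it 3 immediate early genes rose, with a median of 0.415 (adjusted p = 0.026), and Btg2 rose by 0.848. Of 20 genes of insulin and FoxO signalling, 6 rose and 6 fell, with 16 called when adjusted over the list alone. Igfbp1, a secreted IGF-binding protein, rose by 2.97 and Pygl, the liver glycogen phosphorylase gene, fell by 1.01. That list had a median of -0.11 and a mean of 0.09, and camera put it lower without a call (adjusted p = 0.869).

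Of 12 Kupffer cell markers, 7 fell and 0 rose, with 10 called when adjusted over the list alone and a median of -0.59 (adjusted p = 0.000189, and adjusted p = 0.289 with an estimated correlation). Adgre1, the macrophage antigen F4/80, fell by 0.84 and Timd4, a receptor for dying cells, by 0.81. Without fasted replicate 5 with 0 earlier fasts, 4 Kupffer cell markers fell (median -0.555, adjusted p = 0.000462). Of 12 antigen presentation genes, 4 fell and 0 rose, with 5 called when adjusted over the list alone and a median of -0.25 (adjusted p = 0.0025, and adjusted p = 0.258 with an estimated correlation). The class II genes H2-Ab1 and H2-Aa, which macrophages also express, fell by 1.03 and 0.86. Of 19 interferon response genes, 3 fell and 2 rose, with 7 called when adjusted over the list alone, and the list was not called (median -0.22, adjusted p = 0.0763). Irf1, an interferon-regulated transcription factor, fell by 0.52. Of 12 stellate cell and fibroblast markers, 4 fell and 0 rose, 4 also when adjusted over the list alone, with a median of -0.24 (adjusted p = 0.00575, and adjusted p = 0.168 with an estimated correlation). Col3a1, a fibrillar collagen gene, fell by 0.92 and Lrat, a retinol acyltransferase of stellate cells, by 0.55. Of 11 lymphocyte markers 1 fell, also when adjusted over the list alone (median -0.18, adjusted p = 0.0458, and adjusted p = 0.239 with an estimated correlation). Of 7 adipocyte markers 1 rose, also when adjusted over the list alone (median 0.33, adjusted p = 0.0458, and adjusted p = 0.342 with an estimated correlation). That riser was Plin4, a lipid droplet coat gene, up by 1.85. The lymphocyte call was lost without fed replicates 1, 2 and 5 or fasted replicates 1, 3, 4 and 8 with 0 earlier fasts (adjusted p up to 0.111), with an intensity trend (0.0523), with cyclic loess (0.0524) and without dim genes (0.184). The adipocyte call was lost without fed replicates 2, 5 and 8 or fasted replicate 4 with 0 earlier fasts, or without fed replicate 7 with 2 earlier fasts (adjusted p up to 0.198), with only the groups compared (0.0934) and without dim genes (0.0777).

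The other marker lists were not called. Of 12 sinusoidal endothelial markers 1 rose and 1 fell, with 2 called when adjusted over the list alone (median -0.14, mean -0.06, adjusted p = 0.143), and the riser was Lyve1, a hyaluronan receptor, up by 0.93. Of 7 exocrine pancreas markers 1 rose and 1 fell, with 2 called when adjusted over the list alone (adjusted p = 0.841). Of 6 cholangiocyte, 9 neutrophil and monocyte, 2 erythroid and 9 skeletal muscle markers, 0 were called over all genes and 0 when adjusted over the list alone, with adjusted p of 0.94, 0.958, 0.899 and 0.961 for the lists. The cholangiocyte list had a median of 0.04, but camera put it lower. At unadjusted p under 0.05, 4844 of all genes passed in this comparison.

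In total, 2768 of 22180 genes changed (limma, adjusted p under 0.05), or 12.5%, with 1387 higher and 1381 lower. Of these, 166 rose and 152 fell by more than 2-fold. Genes with near-identical relatives, such as Acot1 and Acot2, Mt1 and Mt2, or Cyp4a14 and Cyp4a31, could share hybridization on these arrays, and their values were not separated further.

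**Figure D1:**
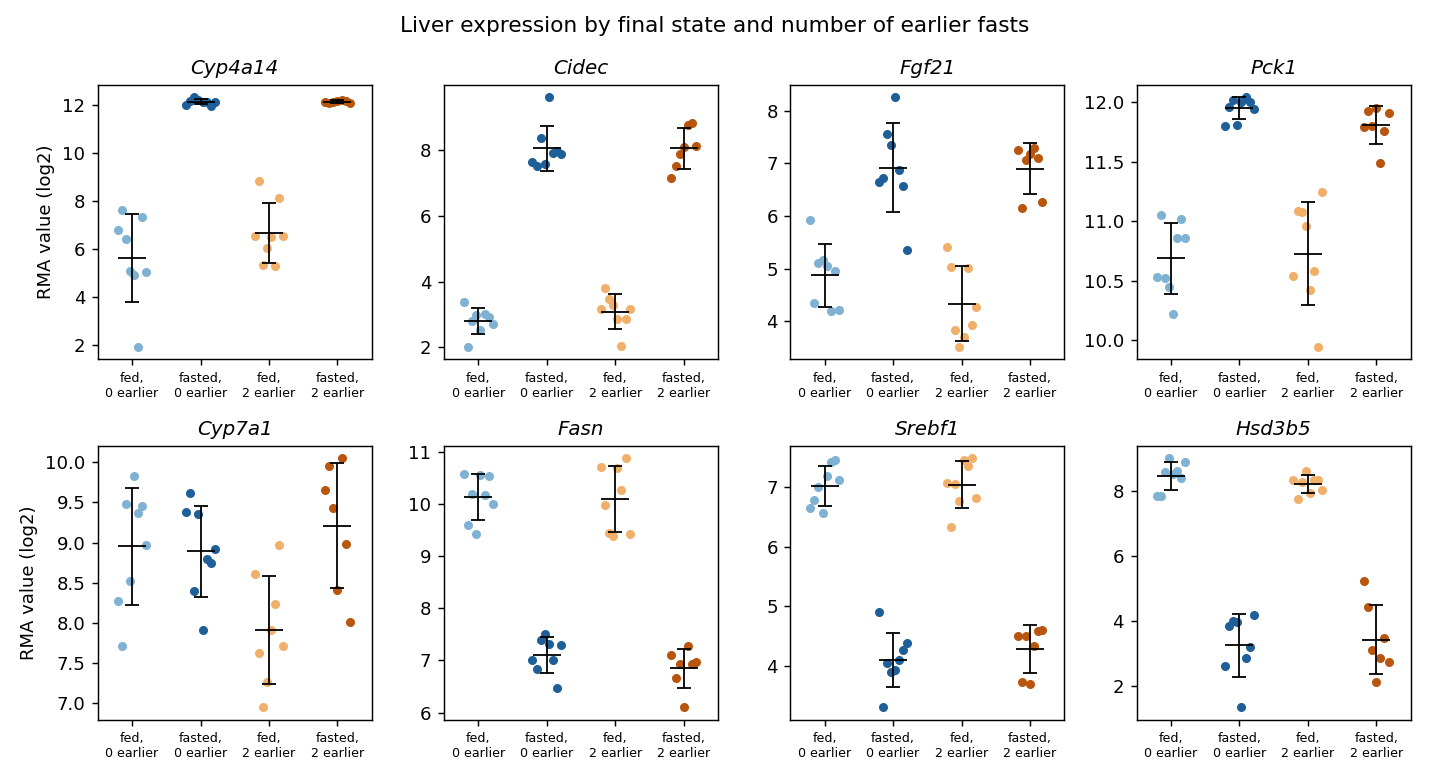
RMA log2 values (y axis) of 8 genes in the 4 groups (x axis: final state and number of earlier fasts), with 1 point per mouse, the group mean as a horizontal bar and its SD as error bars (n = 8, 8, 8 and 7). Cyp4a14 lies between 11.98 and 12.33 in fasted mice with 0 earlier fasts, and Fasn falls from a mean of 10.13 in fed mice to 7.10 in fasted mice with 0 earlier fasts.

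The response to the final fast in mice with 2 earlier fasts asks whether the same fast gives the same response in livers that have been fasted before. Again Cyp4a14 rose most, from 6.65 ± 1.25 in fed mice to 12.15 ± 0.05 in fasted mice (log2, mean ± SD, n = 8 and 7), or 45.1-fold (log2 change 5.50, SE 0.54, adjusted p = 1.51e-09). Cidec rose by 4.94, Acot1 by 4.47, Acot2 by 4.39, and Mt2 by 4.34. Hsd3b5 fell by 4.78, Sqle by 3.64, Fdps by 3.64, and Clec2h, a C-type lectin gene, by 3.55. Fgf21 rose by 2.56 (SE 0.32, adjusted p = 3.12e-07) and Pck1 by 1.07 (SE 0.14, adjusted p = 5.44e-07).

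Of 25 fatty acid oxidation genes, 22 rose and 0 fell (23 called when adjusted over the list alone, median 0.80), with Ehhadh up by 2.72 and Cpt1a by 1.31. Of 28 PPAR-alpha targets, 24 rose and 0 fell (25 called when adjusted over the list alone, median 1.37). Of 4 ketogenesis and ketone transport genes, 2 rose and 0 fell (3 called when adjusted over the list alone, median 0.34), with Slc16a1 up by 1.29 and Acat1, the mitochondrial thiolase gene, by 0.43. Of 16 gluconeogenesis genes, 9 rose and 1 fell (11 called when adjusted over the list alone, median 0.41), with Got1 up by 1.14 and Pcx, the pyruvate carboxylase gene, by 0.62. Of 26 glycolysis and lipogenesis genes, 22 fell and 0 rose (24 called when adjusted over the list alone, median -0.91), and Thrsp fell by 3.41, Fasn by 3.25 and Srebf1 by 2.77. Of 20 cholesterol biosynthesis genes, 18 fell and 0 rose (18 called when adjusted over the list alone, median -1.99), and Insig1 fell by 3.07, Nsdhl by 3.05 and Msmo1, a methylsterol monooxygenase gene, by 2.73. Of 17 glucocorticoid-responsive genes, 10 rose and 0 fell (12 called when adjusted over the list alone, median 0.65), with Cdkn1a up by 3.31. Of 19 male-biased genes, 11 fell and 1 rose (14 called when adjusted over the list alone, median -0.50), and Selenbp2 fell by 2.63 and Nudt7 by 2.25. With an estimated correlation, adjusted p = 1.67e-05, 4.2e-05, 0.00823, 0.00173, 0.00184, 7.32e-05, 0.00823 and 0.016 for these 8 lists in the order given.

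At the preset correlation, 9 other lists had adjusted p between 5.97e-05 and 0.0187, and their calls were lost with an estimated correlation. Of 23 genes of the unfolded protein and integrated stress response, 9 fell and 1 rose (11 called when adjusted over the list alone, median -0.32, adjusted p = 0.326 with an estimated correlation), and Pdia6, a protein disulfide isomerase gene, fell by 0.93. Of 24 genes of the urea cycle and amino acid catabolism, 10 rose and 3 fell (14 called when adjusted over the list alone, median 0.185, adjusted p = 0.326 with an estimated correlation), with Asl up by 1.05. Of 20 autophagy and lysosome genes, 7 rose and 1 fell (10 called when adjusted over the list alone, median 0.10, adjusted p = 0.125 with an estimated correlation), with Bnip3 up by 1.00. Of 11 heat shock protein genes, 4 rose and 0 fell (8 called when adjusted over the list alone, median 0.41, adjusted p = 0.196 with an estimated correlation), with Hspb1 up by 0.79 (0.488 with the mean of its probe sets). Of 19 female-biased genes, 4 rose and 1 fell (7 called when adjusted over the list alone, median 0.07, adjusted p = 0.0677 with an estimated correlation), with Fmo2, a flavin monooxygenase gene, up by 1.42. Without fasted replicate 4 with 2 earlier fasts, the adjusted p for the female-biased list was 0.0504, and with only the groups compared it was 0.0562. Of 12 Kupffer cell markers, 3 fell and 0 rose (3 called when adjusted over the list alone, median -0.445, adjusted p = 0.464 with an estimated correlation). Of 12 stellate cell markers, 3 fell and 0 rose (3 called when adjusted over the list alone, median -0.26, adjusted p = 0.196 with an estimated correlation), and Col3a1 fell by 1.09. Of 19 interferon response genes, 5 fell and 0 rose (9 called when adjusted over the list alone, median -0.26, adjusted p = 0.291 with an estimated correlation), and Irf1 fell by 0.47. Of 12 antigen presentation genes, 4 fell and 0 rose (4 called when adjusted over the list alone, median -0.205, adjusted p = 0.311 with an estimated correlation), and H2-Ab1 fell by 1.09. Adgre1 fell by 0.69 among the Kupffer cell markers, and its call was lost without fed replicate 1 or 7 or without fasted replicate 2 or 5 with 2 earlier fasts (adjusted p up to 0.097).

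With a permutation of array means, the calls of Kupffer cell markers (adjusted p = 0.12) and of the unfolded protein and integrated stress response (adjusted p = 0.0905) were lost too, while cell cycle genes (adjusted p = 0.0144) and adipocyte markers (adjusted p = 0.018) passed. In the remaining lists of this comparison, 0 of 16 immediate early genes and 0 of 22 cell cycle genes were called over all genes, and 0 of each when adjusted over the list alone, with adjusted p of 0.839 and 0.223 for the lists by camera. The immediate early list had a median of -0.01 and a mean of 0.09, and camera put it higher. Among 20 genes of insulin and FoxO signalling, 5 rose and 6 fell (11 called when adjusted over the list alone, median -0.06, mean 0.10, adjusted p = 0.769). Among the other marker lists, 1 of 12 sinusoidal endothelial markers rose and 1 fell (5 called when adjusted over the list alone, 4 of them lower, median -0.10, adjusted p = 0.12), and 1 of 7 adipocyte markers rose (1 called when adjusted over the list alone, median -0.01, mean 0.19, adjusted p = 0.466). Of 11 lymphocyte, 7 exocrine pancreas and 9 skeletal muscle markers, 1 of each fell, also when adjusted over the list alone, with adjusted p of 0.189, 0.679 and 0.351 for the lists. The pancreas list had a median of 0.07 and a mean of -0.08, and camera put it lower. Of 6 cholangiocyte, 9 neutrophil and monocyte and 2 erythroid markers, 0 were called over all genes and 0 when adjusted over the list alone, with adjusted p of 0.864, 0.906 and 0.839. G6pc passed with a log2 change of 0.46 (SE 0.15, adjusted p = 0.041). That call was lost without any 1 of fed replicates 2, 3, 4, 5 and 8 or fasted replicates 2, 3, 4, 5 and 6 with 2 earlier fasts (adjusted p up to 0.124), and in 4 other settings.

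In total, 2569 genes changed (limma, adjusted p under 0.05), or 11.6%, with 1344 higher and 1225 lower, and 145 rose and 151 fell by more than 2-fold. At unadjusted p under 0.05, 4802 passed. Of the genes called in each response, 935 were higher in both (84.0 expected if the calls were independent), 894 were lower in both (76.3 expected) and 2 were called in opposite directions. Arhgap31 rose by 0.34 with 0 earlier fasts and fell by 0.43 with 2, and Ccnjl, which codes for a cyclin-like protein, fell by 0.33 and rose by 0.41. Group means of Ccnjl ran from 1.45 to 1.85, below the array medians of 2.01 to 2.07, so its values lie near the floor. Among 937 genes called only with 0 earlier fasts, 93.1% had the same sign in the other response, and among 738 called only with 2 earlier fasts, 91.7% did. Across all genes, which are not independent replicates, the log2 changes of both responses had a Pearson's r of 0.853 and a Spearman's rho of 0.547. Over the 3506 genes called in either response Pearson's r was 0.953, a value that selecting genes on these same responses raises.

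**Figure D2:**
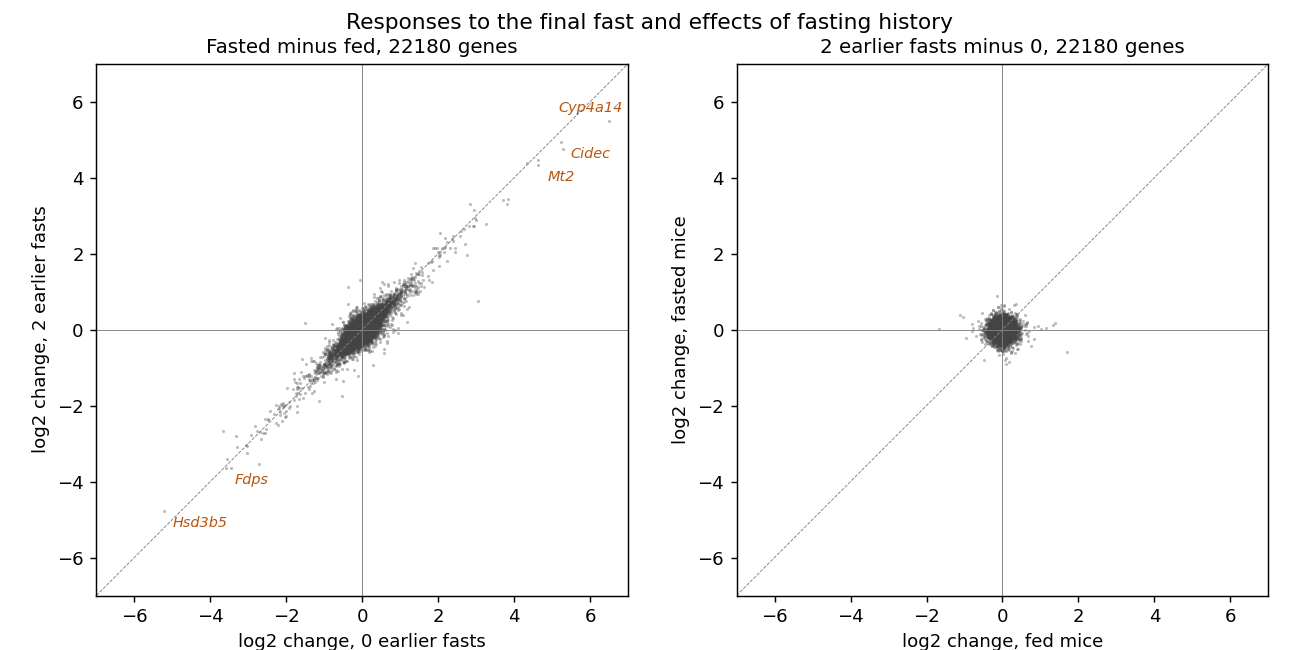
Left, log2 change of each of 22180 genes from fed to fasted with 0 earlier fasts (x axis) and with 2 earlier fasts (y axis); right, log2 difference of mice with 2 from mice with 0 earlier fasts in fed (x axis) and fasted (y axis) mice, with 1 point per gene and a dashed line of equality. The responses to the final fast have a Pearson's r of 0.853, and the differences between histories have one of 0.0343.

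**Figure D3:**
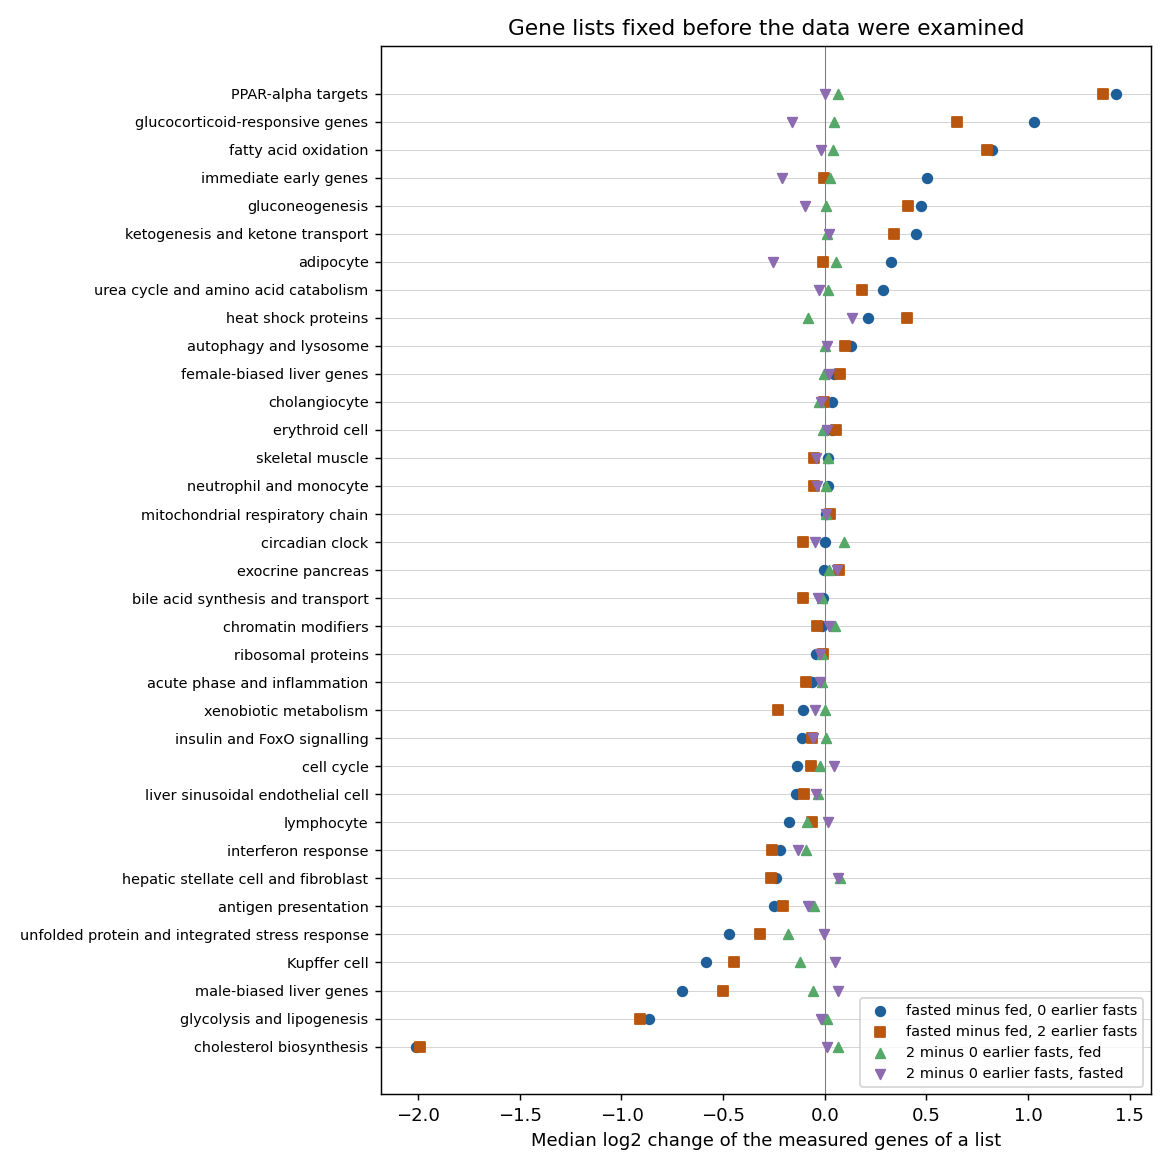
Median log2 change (x axis) of the measured genes of 35 gene lists (y axis), with circles for fasted minus fed with 0 earlier fasts, squares for fasted minus fed with 2 earlier fasts, and triangles for 2 minus 0 earlier fasts in fed mice (upward) and fasted mice (downward). Cholesterol biosynthesis lies at -2.01 and -1.99 and PPAR-alpha targets at 1.43 and 1.37 for the responses to the final fast.

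The comparison of fed mice with 2 and with 0 earlier fasts asks whether past fasts leave a trace once mice have been refed. No transcript passed. Cyp4a14 was at 6.65 ± 1.25 with 2 earlier fasts and 5.64 ± 1.84 with 0 (log2, mean ± SD, n = 8 and 8; log2 difference 1.01, SE 0.52, adjusted p = 0.9), Fasn at 10.10 ± 0.63 and 10.13 ± 0.44 (difference -0.03, SE 0.22, adjusted p = 0.995), Srebf1 at 7.05 ± 0.40 and 7.03 ± 0.34 (difference 0.02, SE 0.19, adjusted p = 0.995), and Pck1 at 10.73 ± 0.44 and 10.69 ± 0.30 (difference 0.04, SE 0.14, adjusted p = 0.993). Fgf21 differed by -0.53 (SE 0.31, adjusted p = 0.906) and G6pc by -0.39 (SE 0.15, adjusted p = 0.856). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 7.91 ± 0.68 with 2 earlier fasts and 8.95 ± 0.73 with 0, a difference of -1.04 (SE 0.32, adjusted p = 0.755).

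Outside predicted and numbered gene models, the 5 genes with the smallest p in fed mice were Zc2hc1c (log2 difference 0.62), Ak4, a mitochondrial adenylate kinase gene (0.39), Strbp (0.28), Cd3eap (-0.45) and H2-M10.4 (0.48). None passed (adjusted p = 0.373 for each). By limma, 0 of 22180 genes passed, with 1245 at unadjusted p under 0.05 against 1109 expected by chance. The 95% interval of the difference lay within 2-fold for 99.7% of genes and within 1.5-fold for 96.5%. Without fed replicate 4 with 0 earlier fasts, Zc2hc1c passed (0.71, adjusted p = 0.0243), and without fed replicate 1 with 2 earlier fasts, Rnd3 passed (0.55, adjusted p = 0.03). Of the 35 lists, camera called 2, the unfolded protein and integrated stress response (median -0.18, adjusted p = 8.01e-06, and adjusted p = 0.876 with an estimated correlation) and chromatin modifiers (median 0.05, adjusted p = 0.0188, and adjusted p = 0.277 with an estimated correlation). In both lists 0 genes were called, over all genes or when adjusted over the list alone. The count of called lists was 1 without fed replicate 6 with 0 earlier fasts, 1 without fed replicate 4 or 6 with 2 earlier fasts, and 6 without fed replicate 7 with 0 earlier fasts. When adjusted over the list alone, 1 gene of all lists was called, Cyp7a1 among 20 genes of bile acid synthesis and transport. Over 35 lists, a call of this kind can arise by chance.

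The comparison of fasted mice with 2 and with 0 earlier fasts asks whether past fasts alter the fasted liver. Cyp4a14 was at 12.15 ± 0.05 and 12.14 ± 0.11 (log2, mean ± SD, n = 7 and 8; difference 0.0098, SE 0.54, adjusted p = 1), and Fgf21 at 6.89 ± 0.48 and 6.92 ± 0.85 (difference -0.02, SE 0.32, adjusted p = 1). The SE of Cyp4a14 comes from 1 variance shared by all 4 groups. Its fed SDs of 1.84 and 1.25 raise that variance, so the SE does not measure the spread of fasted mice. Both fasted means of Cyp4a14 lie near the top of the signal range, where an array may compress differences. Pck1 differed by -0.14, G6pc by -0.22, Cyp7a1 by 0.32, Srebf1 by 0.18 and Fasn by -0.25, and none passed (adjusted p = 1 for each). Outside predicted and numbered gene models, the smallest p was that of Cebpd, a transcription factor of the C/EBP family and a glucocorticoid-responsive gene. Cebpd was at 2.60 ± 0.17 and 3.15 ± 0.31, and did not pass (difference -0.55, SE 0.11, adjusted p = 0.473). Rcc2 followed with 0.41, Asic1 with -0.34, Reg2 with 0.27 and Prss48 with -0.48. Group means of Asic1 ran from 1.436 to 1.779, below the array medians of 2.01 to 2.07, so its values lie near the floor.

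By limma, 0 genes passed between histories in fasted mice, with 996 at unadjusted p under 0.05 against 1109 expected. The 95% interval lay within 2-fold for 99.7% of genes and within 1.5-fold for 96.4%. Without fasted replicate 6 with 2 earlier fasts, 1700025C18Rik passed (0.59, adjusted p = 0.0429). Camera called 4 lists, all lower with 2 earlier fasts: gluconeogenesis (median -0.10, adjusted p = 0.0013, and adjusted p = 0.181 with an estimated correlation), interferon response (median -0.13, adjusted p = 0.0026, and adjusted p = 0.893 with an estimated correlation), immediate early genes (median -0.21, adjusted p = 0.00342, and adjusted p = 0.893 with an estimated correlation) and glucocorticoid-responsive genes (median -0.16, adjusted p = 0.0407, and adjusted p = 0.965 with an estimated correlation). The glucocorticoid call was also lost in 3 settings that kept camera's preset correlation and left out no single array (adjusted p of 0.0529 to 0.095). The count of lists was 2 without fasted replicate 5 with 0 earlier fasts. When adjusted over the list alone, 2 genes were called, Cebpd among 17 glucocorticoid-responsive genes and Mx2, an interferon-induced GTPase gene, among 19 interferon response genes (difference -0.54, SE 0.15). The differences between histories in fed and in fasted mice had a Pearson's r of 0.0343 and a Spearman's rho of 0.0444. They were taken across genes that are not independent replicates. Over the 3506 genes called in either response to the final fast Pearson's r was -0.137. Those genes were selected on the same group means. Such a selection pushes this r below 0 without any history effect, so its sign decides nothing.

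The interaction asks whether the response to the final fast differs with history. Cyp7a1 did not pass in mice with 0 earlier fasts (log2 change -0.06, SE 0.32, adjusted p = 0.949) and rose by 1.30 in mice with 2 (SE 0.33, adjusted p = 0.00521), but the difference between the responses did not pass (1.37, SE 0.45, adjusted p = 0.999). Cyp4a14 differed by -1.0 (SE 0.74), Fgf21 by 0.51 (SE 0.45), Fasn by -0.22 (SE 0.31), Pck1 by -0.19 (SE 0.19), G6pc by 0.16 (SE 0.21) and Srebf1 by 0.16 (SE 0.27), each with an adjusted p of 0.999. Fasted values of Cyp4a14 lie near the top of the signal range with either history, where an array may compress differences. Gadd45g, chosen here after its values were seen, rose by 3.04 with 0 earlier fasts and had a change of 0.76 that did not pass with 2 (adjusted p = 0.539), from fed means of 3.42 ± 0.58 and 5.12 ± 1.98 (SD, n = 8 and 8). The difference of its responses did not pass either (-2.29, SE 0.84, adjusted p = 0.999). Outside predicted and numbered gene models, Arhgap31 and Ccnjl had the smallest p, with differences of -0.77 (SE 0.15) and 0.74 (SE 0.14). Neither passed (adjusted p = 0.135 for each), and the values of Ccnjl lie near the floor. Angel1 followed with -0.65, Ttc9c with 0.52 and Clec2m with -0.46. Group means of Clec2m, 1.772 to 2.089, lie about the array medians of 2.01 to 2.07 and so near the floor too. The numbered model 1700025C18Rik also had an adjusted p of 0.135.

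By limma, 0 genes passed for the interaction, with 1023 at unadjusted p under 0.05 against 1109 expected, and the 95% interval lay within 2-fold for 98.5% of genes and within 1.5-fold for 84.8%. Without fasted replicate 3 with 0 earlier fasts, Angel1 passed (-0.73, adjusted p = 0.0337), and without fasted replicate 6 with 2 earlier fasts, 1700025C18Rik passed (0.83, adjusted p = 0.0243). Camera called 5 lists, and none with an estimated correlation. The response was smaller with 2 earlier fasts for immediate early genes (median -0.33, adjusted p = 0.00116, and adjusted p = 0.612 with an estimated correlation), glucocorticoid-responsive genes (median -0.215, adjusted p = 0.0182, and adjusted p = 0.983 with an estimated correlation), fatty acid oxidation (median -0.06, adjusted p = 0.0371, and adjusted p = 0.983 with an estimated correlation) and gluconeogenesis (median -0.09, adjusted p = 0.0417, and adjusted p = 0.612 with an estimated correlation). It was less negative for the unfolded protein and integrated stress response (median 0.16, adjusted p = 0.0371, and adjusted p = 0.995 with an estimated correlation). At camera's preset correlation with no single array left out, 1 setting each ended the calls of gluconeogenesis (adjusted p = 0.0757), fatty acid oxidation (adjusted p = 0.0563) and the unfolded protein and integrated stress response (adjusted p = 0.209). Without fasted replicate 5 with 0 earlier fasts, 0 lists were called. The count was 1 to 3 without any 1 of fed replicates 3, 4, 5, 6 and 8 or fasted replicates 6, 7 and 8 with 0 earlier fasts, or of fed replicates 2, 4, 5 and 8 or fasted replicates 3 and 5 with 2 earlier fasts. When adjusted over the list alone, 2 genes were called, Cebpd among glucocorticoid-responsive genes (-0.65, SE 0.16) and Ccna2, the cyclin A2 gene, among cell cycle genes (0.52, SE 0.15).

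The history effect over both final states asks for a trace of past fasts that is shared by fed and fasted livers. Adamdec1, a metalloprotease-like gene, had the smallest p outside predicted and numbered gene models. It was higher by 0.36 with 2 earlier fasts (SE 0.08), and did not pass (adjusted p = 0.579). It was at 2.74 ± 0.15 and 2.36 ± 0.23 in fed mice (SD, n = 8 and 8) and at 2.34 ± 0.21 and 2.01 ± 0.26 in fasted mice (SD, n = 7 and 8). The mean of 2.01 lies at the array medians of 2.01 to 2.07, near the floor. Usp50 followed with -0.35, Reg2 with 0.22, Selenom with 0.25 and Hhex, a homeobox transcription factor gene, with 0.51. Cyp4a14 differed by 0.51, Cyp7a1 by -0.36, G6pc by -0.31, Fgf21 by -0.28, Fasn by -0.14, Srebf1 by 0.10 and Pck1 by -0.05, and none passed, with adjusted p between 0.891 and 0.975.

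By limma, 0 genes passed over both states, with 1185 at unadjusted p under 0.05 against 1109 expected, and the 95% interval lay within 2-fold for 99.9% of genes and within 1.5-fold for 99.2%. Camera called 4 lists: the unfolded protein and integrated stress response (median -0.11, adjusted p = 0.000207, and adjusted p = 0.989 with an estimated correlation), interferon response (median -0.09, adjusted p = 0.00249, and adjusted p = 0.61 with an estimated correlation), chromatin modifiers (median 0.06, adjusted p = 0.0155, and adjusted p = 0.314 with an estimated correlation) and gluconeogenesis (median -0.05, adjusted p = 0.0217, and adjusted p = 0.597 with an estimated correlation). In these lists 0 genes were called over all genes and 0 when adjusted over the list alone.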

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

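The tests of precision, of a shift along the fasting response, of the noise, fasting strength and cell types of fasted replicate 5, and all tests of Kupffer cell markers were chosen only after the result was seen.

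Between histories, 0 genes passed in fed mice, in fasted mice, for the interaction or over both states. Too little precision to exclude 2-fold changes is argued against by the 95% intervals for most genes above the 40th percentile of gene means. Their intervals lay inside 2-fold for 99.9% over both states, 99.5% in fed mice, 99.6% in fasted mice and 97.6% for the interaction. Over all genes these shares were 99.9, 99.7, 99.7 and 98.5%. For the interaction it was 96.3% of the genes called in either response to the final fast. Dim genes lie near the floor, where changes may be compressed, so narrow intervals there exclude little. The 40th percentile, 1.78, lies below the array medians of 2.01 to 2.07. Genes just above it are therefore near the floor too, and the shares above it include them. A single aberrant array, or several that array weights would mark down, are argued against as hiding differences, since leaving out any 1 array, or weighting arrays, called at most 1 gene in any of these comparisons. Changes under 2-fold stay open, above all for the interaction, where 84.8% of intervals lay inside 1.5-fold. This share was 79.8% above the 40th percentile and 75.5% among genes called in either response. Of simulated 1.5-fold changes, 52.2% were recovered for the interaction, with 200 independent genes changed. Larger changes stay open for dim genes, for other genes near the floor and for the genes whose intervals reach past 2-fold. A shift along the fasting response was tested with a score. It differed between histories by 2.19% of the fasting effect in fed mice and by -4.9% in its response. The value of -4.9% includes fasted replicate 5 with 0 earlier fasts, whose score stood apart from its group.

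For the responses to the final fast, a random split of the arrays can be excluded as the source of the calls: with 0 earlier fasts, only 1 of 100 splits, the real one, gave as many as 2768 genes, and the highest other gave 10. With 2 earlier fasts it was again only 1 of 100, with 2569 genes against 168 in the highest other. In the comparisons of histories 0 genes were called, so 100 of 100 splits gave at least as many by construction, and the splits decide nothing there. The highest other split gave 2 genes in fed mice, 8 in fasted mice, 1 for the interaction and 3 over both states.

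Fasted replicate 5 with 0 earlier fasts stood apart from its group of 8, with the highest values of Cidec (9.58 against 7.51 to 8.35, gap 0.592 of the range), Cyp17a1 (10.5 against 8.99 to 9.42, gap 0.722), the first principal component (36.8 against 18.3 to 24.3, gap 0.674), the fasting score (2.67 against 1.43 to 1.85, gap 0.658) and the immediate early gene mean (5.16 against 3.84 to 4.38, gap 0.588), and the lowest value of PC3, a minor component (-27.9 against -1.85 to 14.1, gap 0.62). It held 219 genes more than 2-fold from its group mean, against 40 to 171 in other arrays, among them the immediate early genes Nr4a1 (8.37 against 2.56 to 4.97) and Jun (8.46 against 4.56 to 6.25). Added cells of the types with marker lists are argued against, since the largest rise of any marker list's median was 0.107 on the log2 scale. The largest falls were -0.438 for adipocyte and -0.296 for Kupffer cell markers. Whether a lower share of such cells plays a part was not tested. A noisier array cannot be told apart, with a median absolute deviation over brighter genes of 1.18 times the median array (0.875 to 1.21 in the others); this test replaced an earlier one on dim genes, whose ratio of 0.994 says little as dim genes lie near the floor. A stronger form of the common fasting response may account for part, as its deviating genes correlated with the response of the other history (r = 0.519 across genes), between the bounds of 0.3 and 0.7 set for this test, so it stays open.

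Kupffer cell markers had a mean 0.42 lower on the log2 scale after the final fast over both histories (permutation p = 0.00313, adjusted p = 0.00782 over 10 marker lists). A lower share of all non-hepatocyte cells in the RNA is argued against as the whole cause, since Kupffer cell markers fell by 0.37 more than sinusoidal endothelial markers (permutation p = 0.00141, and at most 0.0133 without any 1 endothelial marker or with medians), but not as a part of it, since the endothelial mean difference of -0.06 (permutation p = 0.282) was -0.15 without Lyve1 (permutation p = 0.00423). The means of stellate cell, lymphocyte and exocrine pancreas markers were lower too, with differences of -0.26 (permutation adjusted p = 1e-04), -0.15 (7e-04) and -0.09 (0.0306). The adipocyte mean was higher (0.30, permutation adjusted p = 1e-04). Plin4, up by 1.85 with 0 earlier fasts, was the only adipocyte marker called in either response. Cela1, down by 0.92 with 0 earlier fasts, was the only pancreas marker called lower, and Ctrb1 rose there by 0.345. The means of Ctrb1, 1.654 in fed and 1.998 in fasted mice with 0 earlier fasts, lie near the floor. Neither list is therefore shown to move as a whole. No single array carries the fall over both histories, as leaving out any 1 array gave a permutation p of at most 0.00665, but with 2 earlier fasts alone the difference of -0.35 did not pass (permutation adjusted p = 0.12 over 35 lists). A lower share of Kupffer cells and of other cells whose markers fell, several arrays together, fewer Kupffer cells alone, or less marker RNA in each cell stay open and were not tested.

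Chance flags about 1 in 20 groups in this way, so of 152 groups tested 7.6 were expected and 11 were found, 6 of them fasted replicate 5 with 0 earlier fasts. Serpina4-ps1 was lowest in fed replicate 2 with 0 earlier fasts (7.77 against 9.06 to 10, gap 0.577 of the range). Nsdhl was lowest in fed replicate 3 with 0 earlier fasts (8.51 against 8.94 to 9.19, gap 0.64). Cdkn1a was lowest in fed replicate 4 with 2 earlier fasts (3.38 against 3.91 to 4.3, gap 0.581). Pck1 was lowest in fasted replicate 5 with 2 earlier fasts (11.5 against 11.8 to 12, gap 0.576). G6pc was highest in fasted replicate 4 with 2 earlier fasts (11.1 against 10.3 to 10.6, gap 0.618).

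The response to the final fast differed between histories for 5 lists by camera's test of the interaction, with median differences of -0.0613 for fatty acid oxidation, -0.0859 for gluconeogenesis, -0.215 for glucocorticoid-responsive genes, 0.159 for the unfolded protein and integrated stress response and -0.332 for immediate early genes. None of the 5 was called with an estimated correlation, with a permutation of array means, or without fasted replicate 5 with 0 earlier fasts. Among 16010 probe sets with no gene symbol, 395 changed with the final fast in mice with 0 earlier fasts and 395 in mice with 2. Among 1814 probe sets with several gene symbols, 154 and 126 changed. Between histories, 0 of either kind passed by limma, with 1011 and 118 in fed mice and 767 and 92 in fasted mice at unadjusted p under 0.05. Over both states 995 and 118 passed that unadjusted threshold, and for the interaction 770 and 72. Chance alone would pass a share of about 0.05. Counts in fed mice and over both states lay above that share, and those for the interaction below it.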

How the results depend on the processing

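The test of list means per array, the test of same-number arrays, the adjustment over genes of the mean fasting response and the fit of all probe sets were chosen only after the results were seen. Planned settings other than the threshold and the single arrays left out gave 2545 to 3009 genes with 0 earlier fasts, 2372 to 2876 with 2, and 0 for every comparison of histories; all probe sets gave 3035, 2793 and 0. At an adjusted p under 0.01, 1847 and 1692 genes remained, a stricter threshold by construction. The correlation of the responses was 0.89 without dim genes against 0.853, by construction a correlation over fewer dim genes. Arrays with the same replicate number deviated from their group means together slightly more than others, with a mean r of 0.0283 over 45 pairs (3 over 0.1) against -0.00399 over 315 pairs (6 over 0.1), a difference of 0.0323 (permutation p = 2e-04), and 9 of 31 arrays correlated best with their own number. The labels do not say what a number marks, and arrays were not treated as paired. Within each group the numbers rise with the order of the samples in the series. What that order reflects is not given, and a drift along it was not tested. With the replicate number as a block, 2812 and 2584 genes were called for the responses and 0 in each comparison of histories. The block gave 20, 17, 2, 3, 4 and 4 lists against 20, 17, 2, 4, 5 and 4, without glucocorticoid-responsive genes in fasted mice (adjusted p = 0.095) and gluconeogenesis for the interaction (adjusted p = 0.0757). Adjusted over only the 4247 genes called for the mean fasting response, 0 passed between histories (smallest adjusted p 0.146, 0.124, 0.261 and 0.166).

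With an estimated correlation, 9 and 8 lists were called for the responses to the final fast and 0, 0, 0 and 0 between histories, since camera then allows for genes that vary together. A permutation of list means per array called 20 and 17, then 0, 0, 0 and 0. Against camera, it lost heat shock proteins and gained xenobiotic metabolism (adjusted p = 0.0302) with 0 earlier fasts, and with 2 it lost Kupffer cell markers and the unfolded protein and integrated stress response and gained cell cycle genes and adipocyte markers. Array weights gave 3 lists for the interaction against 5, and the cause was not tested. Glucocorticoid-responsive genes in fasted mice were also not called with only the groups compared (adjusted p = 0.0789) or with cyclic loess (adjusted p = 0.0529). Chromatin modifiers over both states were not called with the mean of all probe sets (adjusted p = 0.0505). Without dim genes, the circadian clock was called for the interaction (adjusted p = 0.0483) and antigen presentation over both states (adjusted p = 0.0234). Leaving out 1 array gave 2439 (without fasted replicate 5 with 0 earlier fasts) to 2807 and 2277 to 2613 genes for the responses, 0 to 1 gene in fed mice, in fasted mice and for the interaction, and 0 to 0 over both states. Correlations ran from 0.844 to 0.854 and from 0.0195 to 0.0518. Lists ran from 18 to 21, 16 to 19, 1 to 6 in fed mice, 2 to 6 in fasted mice, 0 to 6 for the interaction and 3 to 5 over both states, and the cause was not tested.

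G6pc in mice with 2 earlier fasts lost its call with an intensity trend (adjusted p = 0.0532), with only the groups compared (0.0974), with the block (0.0764) and with cyclic loess (0.0562). Over the named genes, 1785 values kept their side of the threshold and 27 lost it in settings with all arrays, and 8007, 144 lost and 2 gained with 1 array left out. For lists these numbers were 1748, 66 lost and 6 gained, and 6372, 92 lost and 46 gained. Values that were never called count as kept in these totals. The totals with 1 array left out also include arrays outside the groups compared, which enter only the shared variance. They therefore overstate how stable the called values are. No called value changed direction. Signal over background limits dim genes, for which no detection call was used, and genes near the top, where differences may be compressed.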

Other observations

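The tests of a lasting shift and of a larger or smaller response, and the bootstrap intervals, were chosen only after the result was seen.

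Genes of bile acids and foreign compounds went both ways with the final fast. Of 20 genes of bile acid synthesis and transport, 4 rose and 5 fell with 0 earlier fasts (12 called when adjusted over the list alone, median -0.01, adjusted p = 0.744) and 5 rose and 5 fell with 2 (12 called when adjusted over the list alone, median -0.11, mean 0.03, adjusted p = 0.724). Cyp8b1, which sets the cholic acid share of bile acids, rose by 1.35 and 1.33, and Abcb11, the bile salt export pump, fell by 1.15 and 1.07. Of 28 genes of xenobiotic metabolism, 8 rose and 8 fell with 0 earlier fasts (18 called when adjusted over the list alone, adjusted p = 0.168, and 0.0302 with a permutation of array means) and 7 rose and 9 fell with 2 (23 called when adjusted over the list alone, adjusted p = 0.0532). Cyp2c55, a cytochrome P450 gene, fell by 2.42 and 2.15 (-1.64 and -1.47 with the mean of its probe sets), and Gstm3, a glutathione transferase gene, by 1.82 and 1.56. With 0 earlier fasts Nr1i3, the nuclear receptor CAR, rose by 1.39, and with 2 Alas1, the first enzyme of haem synthesis, rose by 1.26. The mean of Alas1 was also higher after the final fast with 0 earlier fasts (9.865 against 9.027 in fed mice). Genes given for 1 history met the naming rule only there, which does not show that the responses differ.

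Of 20 circadian clock genes, 1 rose with 0 earlier fasts (1 called when adjusted over the list alone, adjusted p = 0.686), and 2 rose and 5 fell with 2 (8 called when adjusted over the list alone, adjusted p = 0.387). Per1, also a glucocorticoid-responsive gene, rose by 2.01 and 1.68, and Bhlhe40, a repressor in the clock, fell by 1.31 with 2 earlier fasts. With 0 earlier fasts the mean of Bhlhe40 was also lower in fasted mice (6.731 against 7.412), without a call. Of 22 acute phase and inflammation genes, 3 rose and 5 fell with 0 earlier fasts (9 called when adjusted over the list alone, adjusted p = 0.428) and 3 rose and 6 fell with 2 (10 called when adjusted over the list alone, adjusted p = 0.19). Lcn2, the lipocalin gene, rose by 1.15 and 1.24 and Steap4, a metalloreductase gene, fell by 1.05 and 1.13. Of 35 chromatin modifiers, 1 rose and 3 fell in each response (5 and 4 called when adjusted over the list alone, adjusted p = 0.94 and 0.351; with 0 earlier fasts the median was -0.01, the mean 0.0063 and camera's direction lower), and Kdm6b, a histone demethylase gene, rose by 0.63 with 0 earlier fasts (0.331 with the mean of its probe sets). Of 20 ribosomal protein genes, 2 and then 1 fell (2 and 1 called when adjusted over the list alone, adjusted p = 0.168 and 0.351). Of 24 respiratory chain genes, 1 rose and 1 fell, then 1 rose and 2 fell (2 and 3 called when adjusted over the list alone, adjusted p = 0.94 and 0.742), and Cycs, the cytochrome c gene, rose by 0.36 and 0.42.

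Past fasts may leave a small shift along the fasting response that no single gene shows. A fasting score was formed as the mean of 148 genes that rose minus the mean of 151 that fell by more than 2-fold over both histories. Its group means were -1.74 ± 0.18 in fed and 1.74 ± 0.41 in fasted mice with 0 earlier fasts (SD, n = 8 and 8), and -1.66 ± 0.15 and 1.65 ± 0.36 with 2 (SD, n = 8 and 7). In fed mice the score differed between histories by 2.19% of the fasting effect of 3.4 (95% interval -3.1 to 7.49%, exact permutation p = 0.378, adjusted p = 0.67 over 3 comparisons), so a lasting shift of more than 10% is argued against. A larger or smaller response to the final fast cannot be told from none, with a difference of -4.9% (95% interval -19.9 to 7.87%, permutation p = 0.46, adjusted p = 0.67). In fasted mice the difference was -2.7% (95% interval -15.5 to 9.43%, exact permutation p = 0.67). Fasted replicate 5 with 0 earlier fasts had a score of 2.67, against 1.43 to 1.85 in the rest of its group. It raises the mean of that group, and the differences of -4.9% and -2.7% were not taken without it.

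Fed mice might differ in how far they had gone into a fast, in which case arrays with a higher mean of PPAR-alpha targets would have a lower mean of glycolysis and lipogenesis genes. Over all fed arrays together the data went against such a negative correlation. Over 16 arrays Pearson's r was 0.358 (bootstrap 95% interval -0.0219 to 0.647, permutation p = 0.17) and Spearman's rho 0.338 (permutation p = 0.201). Without the 2 arrays farthest from the median, r was 0.417. Within the fed groups of 8, r was 0.412 (bootstrap 95% interval -0.516 to 0.917, exact permutation p = 0.304) with 0 earlier fasts and 0.366 (bootstrap 95% interval -0.303 to 0.84, exact permutation p = 0.363) with 2, too wide to exclude it within either group, and rho was 0.5 and 0.262 (exact permutation p = 0.216 and 0.536). Without the 2 arrays farthest from the median of their group, r was 0.338 and 0.0467, so within the group with 2 earlier fasts it rests on those arrays. The 3 Pearson correlations had adjusted p of 0.363. Both lists were taken as plain array means, so any factor shared by the genes of an array could raise r. Whether fed mice differed in how far they had gone into a fast therefore stays open.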
